A study of Homo sapiens with 9 samples.

How the data were processed

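Plasma pools from 3 subject groups were tested for antibodies to printed human proteins: patients with metastatic osteosarcoma, patients with nonmetastatic osteosarcoma, and control subjects without cancer. The labels describe the controls as healthy or noncancerous pediatric patients, so the control pools may hold plasma of children with other conditions. Osteosarcoma is a malignant tumour of bone. Each group had 3 arrays, 9 in all. Per the labels' protocols, 10 µl of plasma was diluted 500-fold in 5 ml of buffer and incubated on a blocked human protein microarray (ProtoArray). Bound antibody was stained for 90 minutes with an Alexa Fluor 647 goat antibody to the heavy and light chains of human IgG, diluted 2000-fold. Such an antibody can also bind the light chains of other immunoglobulin classes. The values are therefore fluorescence of bound antibody, not amounts of a protein in plasma. The labels do not say whether the 3 arrays of a group held separate pools, so p-values measure only the spread between these arrays, which may be technical.

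The deposited intensity values are unnormalized scanner output. Per the file headers, PerkinElmer ScanArray Express measured 19200 spots per array in 1 channel with adaptive-circle spot finding, at laser power 90 and photomultiplier setting 65 on every array. The headers list a scaling to the total with a factor of 1, so the deposited intensities had not been rescaled. Each spot's median foreground, median local background and background SD were used. The percent of saturated pixels was deposited for each spot by the same software, but a spot was counted as saturated only where its median foreground lay at the scanner's maximum. Of the spots, 16536 were named on the array as human proteins and 2664 held controls or nothing. The authors' deposited value table holds log2 values of these 16536 spots. Set against the scanner values, they equalled log2 of foreground minus local background to within 5.00e-09, with no scaling between arrays, and were missing for 0.0726 to 2.95% of spots per array, where that difference was not above 0. The medians of its 9 columns ran from 10.82 to 12.06. That table served only as an alternative. The submitters' data processing beyond these headers is not given in the sources used here.

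The 16536 spots formed 8217 features (a printed preparation), of which 8173 were printed as 2 spots and 44 more often. Of the features, 26 were purified antigens printed under their own names and 241 carried a supplier's catalogue number. The purified antigens include preparations named influenza A, DNA, rRNA and cardiolipin, which are not human proteins. They are counted with the printed human proteins throughout. The other 7950 are called clone-made here: 7694 carried the identifier of an open reading frame clone and 256 carried none. Gene symbols came from matching the printed accessions, without versions, to a table of RefSeq genes. Of 7991 accessions, 4282 matched, so 4497 features had a symbol and 3720 kept the accession as printed. Gene coordinates were not used. A feature that a rule on human samples excludes (1 of 8217) was not reported.

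Background was corrected with normexp (offset 50) over all spots, control spots were left out, and log2 values were quantile-normalized between arrays and averaged over the spots of a feature. limma 3.58.1 (lmFit and eBayes with an intensity trend, R 4.3.3) fitted the means of the 3 groups to all 9 arrays, and 4 contrasts were tested two-sided with Benjamini-Hochberg adjustment over the 8217 features at 0.05. No label states a test. A feature counted as above background on an array where the foreground of most of its spots exceeded the local background by 2 background SDs. For a feature printed as 2 spots, both had to do so. It counted as reactive where its normalized signal lay more than 3 robust SDs above the array's median. Array summaries were compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 arrays against 3 or below 0.0119 with 6 against 3. No arrays were copies of each other: the highest correlation between 2 arrays was 0.905, and at most 2.32% of spots had identical values.

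For 1 array the replicate number in its title differs from that in its description, and the numbers of the titles were used, which make the replicates distinct within a group. These numbers follow the scan day in the file headers, so that each of 3 scan days held 1 array of each group. Replicates 1 and 2 were of print lot 1 and replicate 3 of print lot 2. Deviations from the group means correlated between same-day arrays with r from 0.16 to 0.79 and between arrays of different days with r from -0.66 to 0.56. The same-day values lay above 0.1 in every pair, the limit set for it, so the numbers were taken to pair the arrays. The ranges overlap. Replicate 3 was the only print lot 2 array of each group, so a lot effect alone could raise correlations between arrays of the same number. Within print lot 1, same-day values ran from 0.16 to 0.48, below the highest value between days. The limit thus does not tell scan day from print lot. The fit set before the data were examined has no block, and the fit with the replicate number as a block is given beside it for the counts and for the calls it moves among the features named.

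Protein lists were fixed before the data were examined and tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, for every list of at least 5 measured features, adjusted over the 16 lists tested in a contrast. The list of protein kinases was void, since it rested on gene descriptions that the array files do not hold, and took in 0 features. The text names, by a rule set at the same time, features that passed the test and were reactive in at least 2 arrays of a group compared, up to 15 per direction. Where under 10 features qualified, which held in all 4 contrasts, the rule adds up to 10 reactive features per direction by unadjusted p. It also takes in up to 4 members per list past the threshold, or 2 examples where none was. Other features past the threshold are said to have been chosen after their values were seen.

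The alternatives were the foreground without background correction, plain subtraction, an offset of 16, median scaling, cyclic loess, a robust linear model fitted on control spots, 2 filters on dim features, eBayes without trend or made robust, fits on the groups of a contrast alone, the replicate number or the print lot as a block, the authors' value table, a threshold of 0.1, reactive limits of 2 and 5 robust SDs, and leaving out each array in turn. The arrays of print lot 1 alone, no scaling between arrays, and the purified antigens as a list were added after the data were seen. The fit was tested on simulated data: values drawn around the real means of the 8217 features, with 200 changed. The scan-day effects estimated with the replicate block, and the spread left after it, were built into these values. Higher recovery with the block was therefore set by the simulation and gives no reason to prefer that fit. Without the block the fit recovered 27, 32 and 18% of features changed by 1 log2 unit, and 90, 92 and 89% of those changed by 2, for metastatic minus control, nonmetastatic minus control and metastatic minus nonmetastatic. With the block it recovered 79, 80 and 85% and 99, 100 and 100%. False calls numbered 1, 1 and 0 of 118, 125 and 107 calls without the block, and 11, 9 and 19 of 189, 189 and 204 calls with it. With the block they thus made 5.82, 4.76 and 9.31% of calls, above the 5% aimed at in the first and last comparison. Features said below to pass only with the block carry this limit.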

Results

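The arrays compare antibody binding in pooled plasma from 3 control arrays, 3 metastatic osteosarcoma arrays and 3 nonmetastatic osteosarcoma arrays, and the series title names dysregulated proteins in metastatic disease as the question. The median signal of the printed human proteins, after subtraction of the local background, lay between 1793 and 4258 scanner units per array. Between 87.3 and 97.7% of features stood above background on each array. Arrays are few, and their number limits the precision of every value below.

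Before any scaling between arrays, the printed proteins gave more signal on the metastatic arrays than on the control arrays of the same scan day. The medians were 2989.5 against 1908 units on day 1, 2585 against 1848 on day 2, and 4258 against 2861.5 on day 3. The mean difference was 0.57 ± 0.08 on the log2 scale (SD, n = 3 days), or 1.48-fold. The nonmetastatic arrays differed from the controls by 0.08 ± 0.11. The exact permutation test over arrays gave p = 0.2 for metastatic against control (adjusted p = 0.413) and p = 0.7 for nonmetastatic against control (adjusted p = 0.7), with 0.1 the smallest p possible. This test did not use the pairing by scan day, so its p also takes in the spread between days. The difference was not alike over the preparations: the median log2 difference was 0.56 ± 0.10 for clone-made features, 0.0005 ± 0.12 for catalogue features and -0.09 ± 0.13 for purified antigens (SD, n = 3 days). Over the 17 features that were reactive on all 9 arrays, the median difference was -0.01. Quantile normalization removes this shift. After normexp and without scaling, the median of all features differed by 0.71 for metastatic minus control and 0.10 for nonmetastatic minus control, and every difference given below is relative to that shift. For metastatic minus control, nonmetastatic minus control, metastatic minus nonmetastatic and both patient groups minus control, the median of all features was 0.40, 0.04, 0.36 and 0.21 with a robust linear model on control spots and 0.58, 0.07, 0.50 and 0.32 in the authors' value table.

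**Figure D1:**
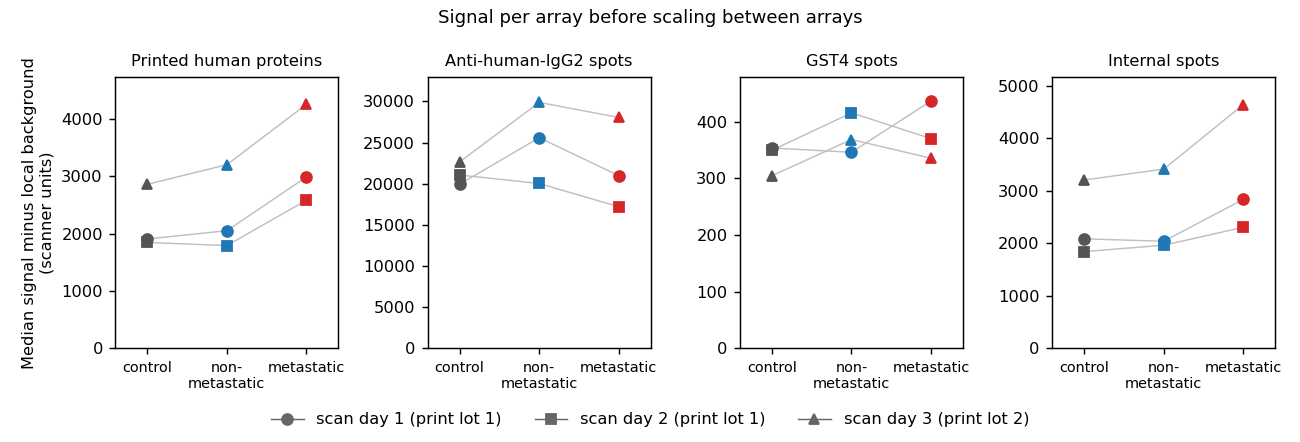
Median signal minus local background (scanner units, vertical axis) of the printed human proteins and of 3 kinds of control spot, for each of the 9 arrays by group (horizontal axis); symbols mark the scan day and lines join arrays of a day. The printed proteins were brighter on the metastatic than on the control array on all 3 days (2989.5 against 1908, 2585 against 1848 and 4258 against 2861.5 units), and so were the GST4 and Internal spots, while Anti-human-IgG2 spots were brighter on days 1 and 3 but not on day 2. GST4 was the only kind of GST spot brighter on all 3 days: GST3, GST6 and GST7 spots were brighter on 2 days, and GST5 and GST8 spots on 1. Buffer, BSA and GST spots together moved by -1.33 ± 30.6 units (SD, n = 3 days).

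**Figure D2:**
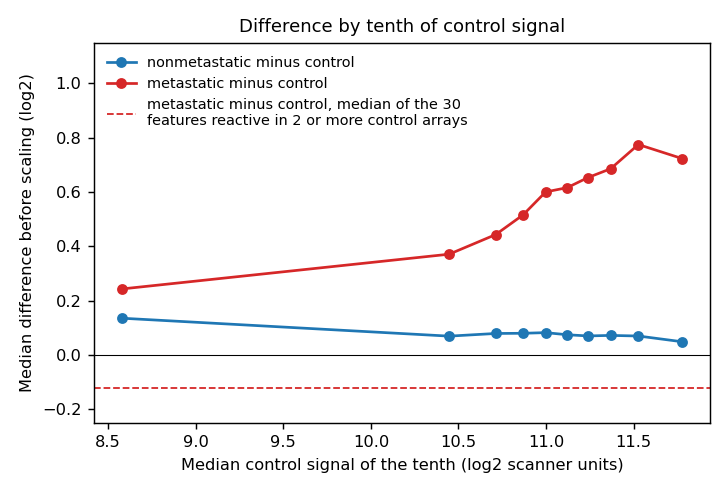
Median log2 difference before scaling (vertical axis) against the median control signal (horizontal axis, log2 scanner units) in 10 groups of features ordered by control signal, for each patient group minus control; the dashed line is the median of the 30 features reactive on at least 2 control arrays. The metastatic minus control difference ran from 0.24 in the dimmest group to 0.77 in the ninth and 0.72 in the brightest, and was -0.12 in the 30 reactive features.

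Few features stood out from the bulk. Each array had 31 to 33 reactive features, and 60 features were reactive on at least 1 array. Quantile normalization gives all arrays the same distribution and so nearly the same count, which therefore compares nothing (metastatic minus control -0.667, exact permutation p = 0.7; nonmetastatic minus control 0, exact p = 1). With arrays scaled only to the same median, the metastatic arrays had a mean of 18.3 reactive features and the control arrays 41.0 (exact permutation p = 0.1, the smallest possible). This count is relative to each array's own median and spread. Before scaling, the median of the printed proteins was higher by 0.57 (log2) on the metastatic arrays, while features reactive on all 9 arrays differed by a median of -0.01. A raised bulk lowers the count, which therefore does not show that fewer antigens were bound. The 17 features reactive on all 9 arrays included the clone of TRIM21, a receptor inside cells that binds the constant part of IgG. Its spots were saturated on all 9 arrays. The purified Ro-52 antigen, which is the same protein, measured 9.07 ± 0.43 on the log2 scale (SD, n = 9) and was above background on 1 array. PTGR3 and EFNA3, an ephrin, also belonged to the 17, and the rest had no symbol. Features reactive on 3 of 3 arrays of a single group and on no other array were CENPB, LUC7L and BC033711.1 in the control group, TRPT1, CTTN and the RNA polymerase preparation in the metastatic group, and BC033035.1 and BC012109.1 in the nonmetastatic group.

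In the metastatic group, antibody binding to the purified RNA polymerase preparation was higher and binding to purified CENPB was lower than in the control group. CENPB, a centromere protein and a known autoantigen in systemic sclerosis, fell from 15.16 ± 0.47 in the control group to 11.67 ± 0.29 (log2 signal, SD, n = 3), an 11.3-fold lower signal (log2 difference -3.50, limma adjusted p = 0.000243). The purified preparation named RNA polymerase, whose content is not given in the sources used here, rose from 10.14 ± 0.45 to 13.48 ± 0.35, or 10.1-fold (adjusted p = 0.00071). TRPT1, a tRNA phosphotransferase, rose 5.09-fold (adjusted p = 0.00385), and CTTN (cortactin), which binds actin filaments, rose 2.23-fold (adjusted p = 0.0112). BC014975.1 and BC063451.1 were the other features that rose, by 3.14-fold and 2.37-fold.

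Of the 8217 features, 25 passed the test for metastatic minus control, 5 higher and 20 lower. Of these, 9 were reactive on at least 2 arrays of a group compared. With the replicate number as a block, 49 passed, 10 higher and 39 lower, and these included all 25. Each of the 25 parted the arrays of the groups compared without overlap, so the same sign on all 3 scan days follows and adds no support. Over all 8217 features 13.7% did so, against 10% by chance. Among the features that fell were 2 more reactive ones with a symbol, LUC7L, a splicing factor (2.72-fold, adjusted p = 0.0254), and G3BP1, a protein of stress granules (2.34-fold, adjusted p = 0.02). TNFSF13B, the B-cell survival cytokine BAFF, fell from 11.68 ± 0.02 to 10.50 ± 0.02 (adjusted p = 0.00705), and MAPRE2, which binds microtubule ends, fell 2.32-fold (adjusted p = 0.0235). Over the other settings these log2 differences shrank to as little as -0.37 and -0.34, and they passed in 18 and 15 of 26. Several protein kinases printed under catalogue numbers also fell. CDK1, the main mitotic kinase, fell 5.89-fold (adjusted p = 0.0448), and, among features chosen after their values were seen, STK17A fell 9.02-fold (adjusted p = 0.00126), DYRK3 6.62-fold (adjusted p = 0.0012) and PRKCB 3.04-fold (adjusted p = 0.0366). STK17A was above background on 2 of 3 metastatic arrays and DYRK3 on 1 of 3. Also chosen in that way, COPZ1, CCDC69, OARD1 and NAP1L5 fell by 2.15-fold to 3.76-fold. Of the 7 features without a symbol that fell, BC026346.1 (3.04-fold) was reactive on 2 control arrays, and BC046151.1 (6.10-fold) was chosen after its values were seen. TWF1, an actin-binding protein that was reactive on 2 metastatic arrays, was 2.80-fold brighter in the metastatic group, with an adjusted p of 0.123, or 0.045 with the block. TTK, a spindle checkpoint kinase printed under a catalogue number, had a log2 difference of -2.18, with an adjusted p of 0.0747, or 0.00718 with the block. MYLK2, a myosin light chain kinase chosen after its values were seen, had a log2 difference of -1.27, with an adjusted p of 0.0783, or 0.0231 with the block.

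No other preparation of CDK1 or PRKCB passed in limma. Of the 2 other CDK1 features, that above background on all 9 arrays differed by 0.26 (log2), and the dimmer, above background on 3 of 9, by -0.09. The other PRKCB features differed by -0.73, in the direction of the called feature, and by 0.11 and 0.59. Whether the RNA polymerase preparation holds the subunits printed elsewhere on the array is not known. The 11 features of such subunits ranged from -0.56 to 0.44, with 0 past the threshold in limma and 1 at an unadjusted p under 0.05. The count of 25 was 6 without control replicate 1, 7 without control replicate 2, 6 without metastatic replicate 1 and 15 without metastatic replicate 2. It was 14 (7 higher, 7 lower) with a robust linear model on control spots, 10 (7 higher, 3 lower) with the authors' unscaled value table, 54 (19 higher, 35 lower) on the arrays of print lot 1 alone, 59 (13 higher, 46 lower) with the print lot as a block, and 1500 (1490 higher, 10 lower) with no scaling after normexp.

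In the nonmetastatic group, CENPB was lower and PFKFB1, LARP6 and SMAD3 were higher than in the same control arrays. CENPB stood at 11.36 ± 0.11 (SD, n = 3), a 13.9-fold lower signal (log2 difference -3.80, limma adjusted p = 0.000108). The patient groups did not differ in CENPB past the threshold (log2 difference 0.31, limma adjusted p = 0.938). Both CENPB differences thus rest on the high signal of the same 3 control arrays and are not separate findings. PFKFB1, an enzyme that sets the level of the glycolysis regulator fructose 2,6-bisphosphate, rose from 12.23 ± 0.22 to 14.16 ± 0.41 (3.82-fold, adjusted p = 0.0102) and was reactive on 3 of 3 nonmetastatic arrays. Features chosen after their values were seen included LARP6, which binds collagen mRNAs and rose 3.09-fold, SMAD3, a transducer of TGF-beta signals that rose 2.57-fold, and CCDC25, which rose 2.32-fold (adjusted p = 0.0102, 0.0102 and 0.0199). LARP6 and SMAD3 were each above background on 1 of 3 control arrays. Neither was reactive on 2 or more arrays of either group, so their signal did not stand out from the bulk by that measure. A second LARP6 clone differed by 0.60 (log2) and did not pass.

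Of the 8217 features, 16 passed the test for nonmetastatic minus control, 7 higher and 9 lower. Of these, 4 were reactive on at least 2 arrays of a group compared. With the replicate block 44 passed, 20 higher and 24 lower, and these included all 16. Each of the 16 parted the arrays of the groups compared without overlap, as 6.07% of all features did, so the same sign on all 3 days follows. LUC7L (3.05-fold) and TNFSF13B (1.95-fold) fell, with adjusted p of 0.0176 and 0.0242, and so did the catalogue kinases CDK1 (6.89-fold, adjusted p = 0.0385), STK17A (8.73-fold, adjusted p = 0.00361) and DYRK3 (5.13-fold, adjusted p = 0.0055); the last 2 and COPZ1 (4.06-fold) were chosen after their values were seen. STK17A was above background on 1 of 3 nonmetastatic arrays and COPZ1 on 2 of 3. BC053895.1 rose 1.95-fold and was reactive on 2 nonmetastatic arrays, and BC060785.1, chosen after its values were seen, rose 3.09-fold. Some reactive features and list members passed only with the block. They were the influenza A preparation (2.10-fold brighter, adjusted p = 0.639 without and 0.039 with the block), UBQLN2 (2.06-fold brighter, 0.0678 and 0.0268), G3BP1 (log2 difference -0.86, 0.124 and 0.0456), BC033711.1 (-1.48, 0.0665 and 0.0209), TTK (-2.22, 0.0961 and 0.00655) and the kinase PBK (-1.65, 0.529 and 0.0186). Features chosen after their values were seen also rose past the threshold only with the block. They were the RNA polymerase preparation (log2 difference 1.38, adjusted p = 0.131 without and 0.008 with the block), SMAD2 (1.29, 0.0539 and 0.0188) and the catalogue kinases PRKD2 (1.45, 0.121 and 0.0386) and MYLK3 (1.67, 0.235 and 0.00655). The count of 16 was 5 without control replicate 1, 6 without control replicate 2, 10 without control replicate 3, 10 without nonmetastatic replicate 1 and 5 without nonmetastatic replicate 2. It was 3 (1 higher, 2 lower) with the authors' value table, 10 (5 higher, 5 lower) with plain background subtraction, 31 (13 higher, 18 lower) on print lot 1 alone, 50 (24 higher, 26 lower) with the print lot as a block, and 34 (19 higher, 15 lower) with no scaling and the replicate block.

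**Figure D3:**
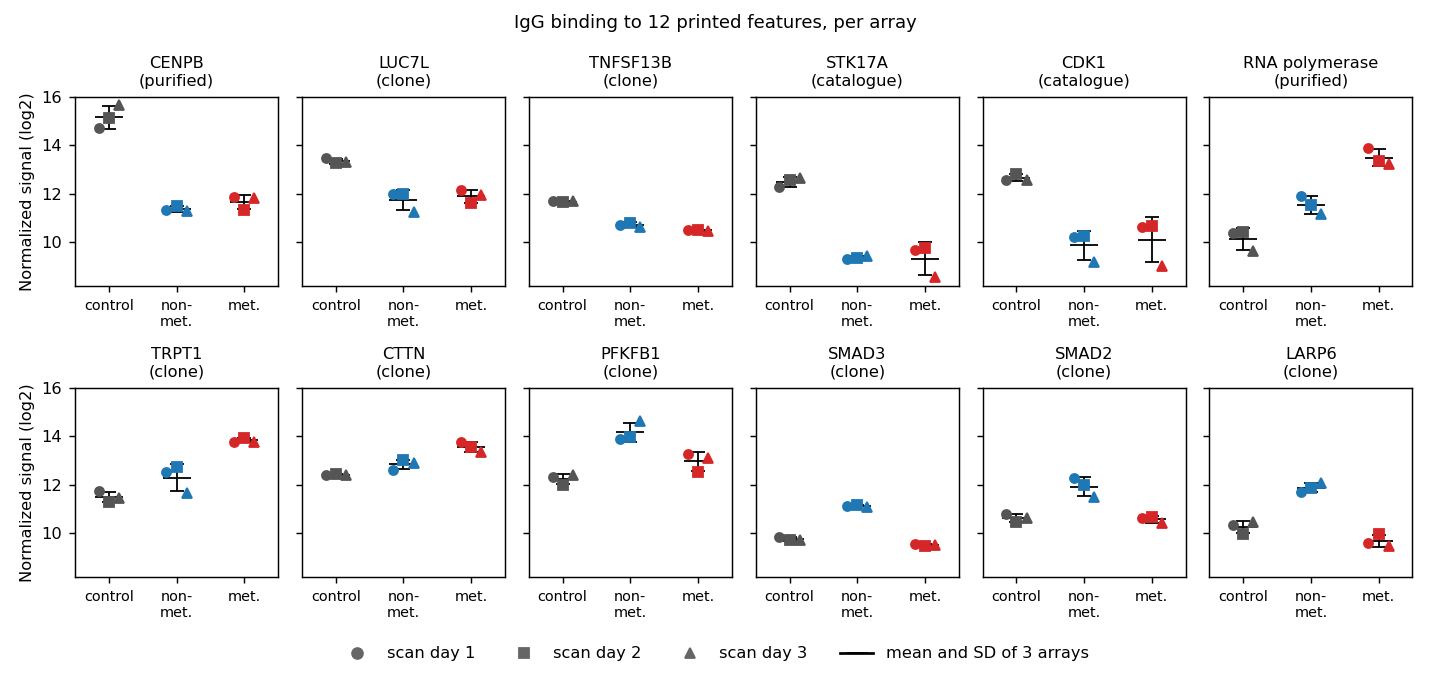
Normalized log2 signal (vertical axis) of 12 features on each of the 9 arrays by group (horizontal axis, nonmetastatic and metastatic shortened to non-met. and met.); symbols mark the scan day, and bars the mean and SD of 3 arrays. CENPB stood at 15.16 in the control group against 11.36 and 11.67 in the nonmetastatic and metastatic groups, the RNA polymerase preparation reached 13.48 in the metastatic group, and SMAD3 reached 11.13 in the nonmetastatic group alone.

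Both patient groups shared 9 features that fell against the control group: CENPB, LUC7L, TNFSF13B, CDK1, STK17A, DYRK3, COPZ1, BC026175.1 and BC046151.1. No feature rose past the threshold in both without the replicate block. With the block 19 fell in both and 1, RNA polymerase, rose in both. Without the block, independent lists of these lengths would share 0.0219 features that fell and 0.00426 that rose. Both comparisons use the same control arrays, and part of the overlap may come from that. Across all features, which are not independent replicates, the 2 sets of differences correlated with r = 0.44, against 0.50 in simulated groups with no effect, and their covariance was 0.0379 against 0.0499.

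When both patient groups were set against the control group, 19 features passed, 4 higher and 15 lower, and with the replicate block 38 passed, 9 higher and 29 lower, including all 19. Of the 19, 8 were reactive on at least 2 arrays of a group compared. CENPB had a 12.5-fold lower signal (log2 difference -3.65, limma adjusted p = 3.96e-05). RNA polymerase rose 5.14-fold (adjusted p = 0.00237), TRPT1 2.99-fold (adjusted p = 0.0206), PFKFB1 2.52-fold (adjusted p = 0.0447) and CTTN 1.73-fold (adjusted p = 0.0447). TRPT1 and CTTN passed in the metastatic but not in the nonmetastatic contrast, and the difference between the patient groups passed for TRPT1 only with the block (adjusted p = 0.0531 without and 0.0144 with it) and for CTTN in neither fit (0.14 and 0.123). PFKFB1 passed in the nonmetastatic but not in the metastatic contrast (log2 difference 0.74, adjusted p = 0.549, or 0.189 with the block). LUC7L, G3BP1 and TNFSF13B fell by 2.06-fold to 2.88-fold. The catalogue kinases STK17A, CDK1, DYRK3 and TTK fell 8.88-fold, 6.37-fold, 5.83-fold and 4.60-fold (adjusted p = 0.000581, 0.0206, 0.000599 and 0.0452), of which STK17A was above background on 2 of 3 metastatic and 1 of 3 nonmetastatic arrays, DYRK3 on 1 of 3 metastatic arrays and TTK on 2 of 3 nonmetastatic arrays. Such folds rest partly on values near background and give no order among these kinases. The TTK clone differed by 0.13 (log2) and the other CDK1 features by 0.35 and -0.02, none past the threshold, with the last above background on only 3 of 9 arrays. C9orf78, chosen after its values were seen, fell 2.45-fold (adjusted p = 0.0488). BC033711.1 and the influenza A preparation passed only with the block (adjusted p = 0.0187 and 0.0473).

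The count of 19 was 6 without control replicate 1, 6 without control replicate 2, 10 without metastatic replicate 1, 12 without metastatic replicate 2 and 11 without nonmetastatic replicate 2. It was 8 (2 higher, 6 lower) with plain background subtraction, 7 (3 higher, 4 lower) with the value table, 10 (5 higher, 5 lower) with no scaling, 42 (12 higher, 30 lower) on print lot 1 alone and 48 (12 higher, 36 lower) with the print lot as a block. Cyclic loess gave 2 higher and 17 lower, and the control-spot model 6 higher and 11 lower.

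Between the patient groups, the metastatic arrays had higher binding to the RNA polymerase preparation and lower binding to LARP6, SMAD3, SMAD2 and the kinases MYLK2 and PRKD2. RNA polymerase measured 13.48 ± 0.35 in the metastatic and 11.52 ± 0.37 in the nonmetastatic group (SD, n = 3; 3.89-fold, limma adjusted p = 0.0297). Among features chosen after their values were seen, LARP6 fell 4.62-fold (adjusted p = 0.00476), SMAD3 3.04-fold (adjusted p = 0.00476) and SMAD2 2.54-fold (adjusted p = 0.0457). The catalogue kinases MYLK2, a myosin light chain kinase, and PRKD2, a protein kinase D, fell 4.49-fold and 3.58-fold (adjusted p = 0.00607 and 0.043), with PRKD2 above background on 2 of 3 metastatic arrays. SMAD3 was above background on 1 of 3 metastatic arrays and LARP6 on 2 of 3. LARP6, SMAD3 and SMAD2 were not reactive on 2 or more arrays of either patient group. UBQLN2, which carries ubiquitylated proteins to the proteasome, fell 2.26-fold (adjusted p = 0.043).

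In total 16 features passed for metastatic minus nonmetastatic, 3 higher and 13 lower. Of these, 5 were reactive on at least 2 arrays of a group compared. With the replicate block 32 passed, 6 higher and 26 lower, including all 16. Each of the 16 parted the arrays of the groups compared without overlap, as 9.24% of all features did, so the same sign on all 3 days follows. The features that rose were RNA polymerase, BC014975.1 (3.19-fold) and BC063451.1 (2.38-fold). BC033035.1 (3.70-fold) and BC012109.1 (3.03-fold) fell and were reactive on 3 of 3 nonmetastatic arrays. CCDC25 and NAP1L5, chosen after their values were seen, fell 2.52-fold and 2.07-fold. TRPT1 (2.90-fold brighter) and PFKFB1 (log2 difference -1.20) passed only with the block (adjusted p = 0.0144 and 0.0177). The PRKD2 clone differed by -0.27 and a second LARP6 clone by -0.90 (log2), neither past the threshold. The count of 16 was 7 without control replicate 1, 9 without control replicate 2, 5 without metastatic replicate 1, 10 without metastatic replicate 2, and 6, 8 and 10 without nonmetastatic replicates 1, 2 and 3. It was 5 (2 higher, 3 lower) with the control-spot model, 1 (1 higher, 0 lower) with the value table, 3 (3 higher, 0 lower) with no scaling, 46 (20 higher, 26 lower) on print lot 1 alone and 45 (6 higher, 39 lower) with the print lot as a block.

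Of the 16 protein lists tested, 0 passed camera in any contrast, with the preset or an estimated correlation or with the replicate block. At an unadjusted p under 0.05, 1, 0, 0 and 1 lists passed for metastatic minus control, nonmetastatic minus control, metastatic minus nonmetastatic and both patient groups minus control. Tumour antigens had the lowest adjusted p for metastatic minus control (0.289; adjusted p = 0.641 with an estimated correlation). Of the 23 tumour antigen features, 0 passed over all features in that contrast and 1, TTK, was lower when adjusted over the list alone. MAGEA4, a cancer-testis antigen of that list, had a log2 difference of -0.72 for metastatic minus nonmetastatic (adjusted p = 0.534). When both patient groups were compared with the control group, 1 tumour antigen (TTK) fell over all features and 2 were lower when adjusted over the list alone. The 21 systemic autoantigen features, 11 of them purified antigens, held 1 that fell, CENPB, in each contrast against the control group, over all features and adjusted over the list alone. The 79 cytokines and growth factors held 1 that fell, TNFSF13B, for metastatic minus control, and 2 were lower when adjusted over the list alone. Of 93 DNA damage and cell cycle features 1 (CDK1) fell in each patient group, with 2 lower when adjusted over the list alone, and 2 (CDK1 and TTK) fell in both groups together. Of 47 cytoskeletal features 1 (MAPRE2) fell for metastatic minus control, with 2 lower when adjusted over the list alone; 1 (MAPRE2) was lower in that way for metastatic minus nonmetastatic and 2 for both patient groups. Of 127 ubiquitin and proteasome features 1 (UBQLN2) fell for metastatic minus nonmetastatic, over all features and adjusted over the list alone, and 1 (UBQLN2 again) was brighter for nonmetastatic minus control when adjusted over the list alone. In that contrast 2 tumour antigens were lower when adjusted over the list alone.

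The remaining lists held no feature past the threshold over all features in any contrast. They were the osteosarcoma-associated genes (44 features), bone and cartilage proteins (17), heat shock proteins (37), glycolytic enzymes (14), histones (25), ribosomal proteins (94), RNA-binding proteins (48), plasma proteins (37), testis-enriched proteins (27) and immunoglobulins with IgG-binding proteins (7). Adjusted over the list alone, the osteosarcoma-associated list had 1 lower feature for metastatic minus nonmetastatic, PDGFRA, a growth factor receptor (adjusted p = 0.209 over all features), and the histone list 1 brighter feature, H2AC20, for nonmetastatic minus control (1.18) and for both patient groups (1.00). In the 7 immunoglobulin and IgG-binding features, FCGR1A, a receptor that binds IgG, differed by -0.24 for nonmetastatic minus control, and FCGR2B by -0.27 for metastatic minus nonmetastatic. fry's directional test passed for 0 of the 16 lists in every contrast. fry's mixed test, which asks whether members change in either direction, passed for systemic autoantigens, cytoskeletal proteins and cytokines in metastatic minus control (adjusted p = 2.71e-05, 0.00264 and 0.0106). It also passed for systemic autoantigens in nonmetastatic minus control and both patient groups (3.48e-06 and 7.17e-07). In metastatic minus control each of these lists held 1 feature past the threshold (CENPB, MAPRE2 and TNFSF13B). Their median log2 differences were -0.03, -0.02 and 0.05. The mixed result may thus rest on few members and does not show a change of a whole list. With the unscaled value table, camera placed systemic autoantigens, tumour antigens and osteosarcoma-associated genes below the other features in metastatic minus control (adjusted p = 5.75e-06, 0.00691 and 0.00691). In that table the clone-made features differed by a median of 0.59 and the 267 catalogue or purified features by 0.04, and 11 of 21, 3 of 23 and 19 of 44 members of these lists were catalogue or purified features.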

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

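The tests on the signal of the metastatic arrays, on the print lots, on the scaling of the kinases, on other kinase preparations and on material of the catalogue preparations were chosen after the results were seen; the test of neighbouring spots was set before its result was seen, but not its limit to brighter ones.

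Control spots, which the tests of features leave out except where an alternative scales on them, were looked at for a signal above the control arrays on all 3 scan days, with a mean rise above a set limit. On the metastatic arrays the spots named Internal, whose content is not given in the sources used here, were brighter by 0.43 ± 0.11 (log2, SD, n = 3 days). On the nonmetastatic arrays this held for BiotinAb spots (0.43 ± 0.56), Calmodulin2 spots (0.53 ± 0.30) and V5Control2 spots (0.58 ± 0.25). Among spots that went the other way on all 3 days, BSA3 spots were dimmer in both patient groups (-0.77 ± 0.47 metastatic, -0.37 ± 0.23 nonmetastatic) and CMK2A spots in the nonmetastatic group (-0.28 ± 0.19). None of these differences was tested.

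The higher signal of the metastatic arrays before scaling was present on all 3 days. Brighter labelling or scanning would raise spots of human IgG and of antibodies to human IgG as much, but the printed proteins rose more than these on each day, by 0.552 ± 0.307 (log2), which argues against it as the whole cause. More binding to the slide surface or to GST would raise buffer, BSA and GST spots in scanner units, but the printed proteins rose by 1073 ± 331 units more. Clone-made features rose more than catalogue features of the same control signal on each day, by 0.491 ± 0.130, as antibodies to material shared by the clone-made proteins (from their production, for example) could bring about. That remains a hypothesis, a difference between the patient groups stays open as untested, and the total IgG of the pools was not measured.

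The arrays also differed by print lot: r ran from 0.79 to 0.90 between arrays of a lot and from 0.58 to 0.68 between lots, and the lot difference correlated between groups with r from 0.59 to 0.79 across features. The array files list a printed amount per spot and lot. If that amount were the cause, its change would explain most of the change in signal, but it explained at most 17.1% of the variance in a group, although its change was measured alike by duplicate spots (r = 0.97). What else differs between the lots stays open, since lot 2 was also scanned on its own day, and no biological explanation was tested, because each lot held all 3 groups.

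The catalogue kinases STK17A, CDK1, DYRK3 and TTK were lower on the arrays of both patient groups, by a median of -2.61 (log2). Scaling between arrays is argued against, since 4 of the 4 stayed lower past the threshold with no scaling and the replicate block, and so is a local fault on the slides, since 53 neighbouring features differed by a median of -0.124, and the 14 of them with a control signal of at least 10.64 (log2), which left room to fall, by -0.118 (quartiles -0.275 and -0.0285). For CDK1 and TTK, the other preparations above background on all control arrays did not fall, the lowest difference being 0.127. Their control signals of 11.06 and 11.59 (log2) lay near the bulk of printed proteins, since array medians before scaling ran from 10.39 to 11.62. These preparations may thus have held no signal of the kinase to lose. Antibodies that bind the kinase in every preparation printed are therefore not excluded. For STK17A and DYRK3 this cannot be told apart either, because 0 such preparations were on the array. Antibodies to material shared by the catalogue preparations may account for part of the pattern. They cannot be told apart from the disease groups, which stay open as untested. The 6 other catalogue features as bright on the control arrays differed by a median of -1.30, against -0.09 for clone-made features of the same control signal. But 6 features picked by that signal are too few to decide, and most of the 237 other catalogue features were too dim to fall as far. The 27 of them with room to fall, by the limit used for the neighbours, differed by a median of -0.404 (quartiles -0.844 and -0.0254). Most of these 27 thus fell far less than the kinases.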

How the results depend on the processing

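No scaling, print lot 1 alone and no scaling with the replicate block were chosen after seeing the data; the other settings were set before the data were examined. The counts of changed features against the main 25, 16, 16 and 19 (metastatic minus control, nonmetastatic minus control, metastatic minus nonmetastatic, both patient groups minus control) moved as follows. With the replicate block, which takes in scan day and print lot together, they were 49, 44, 32 and 38. With the print lot as a block they were 59, 50, 45 and 48, and on print lot 1 alone 54, 31, 46 and 42. With the authors' value table they were 10, 3, 1 and 7, with a robust linear model on control spots 14, 17, 5 and 17, and with plain background subtraction 20, 10, 12 and 8. Without an intensity trend they were 9, 12, 7 and 10, with only the 40 features reactive on at least 3 arrays 9, 6, 7 and 7, which tests fewer features, and with only the groups of the contrast 14, 13 and 6. A threshold of 0.1 gave 38, 22, 22 and 28. No scaling gave 1500, 11, 3 and 10, and with the replicate block 4549, 34, 2706 and 77. Leaving out each array in turn gave 6 to 24, 5 to 18, 5 to 16 and 6 to 19. Where the design itself does not show it (fewer arrays, fewer features, a looser threshold, an unremoved shift), the cause was not tested. Foreground without correction, an offset of 16, median scaling, cyclic loess, the mild filter and robust eBayes kept each count within 1.5 times.

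The lists gave 0 in the main setting, 3, 2 and 2 with the value table for metastatic minus control, metastatic minus nonmetastatic and both patient groups, and 1 on print lot 1 alone (tumour antigens, metastatic minus control, adjusted p = 0.018); leaving out arrays gave 0 throughout. The difference in reactive features per array, metastatic minus control, was -0.667. It was 1.33 without background correction, -2.0 with an offset of 16, 0.333 at 2 robust SDs, -22.7 with median scaling, -13.3 with cyclic loess, -25.3 with the control-spot model and -26.7 with the value table; leaving out arrays gave -1.17 to -0.167. Under quantile normalization this count is fixed by construction. In every setting it is relative to each array's own median and spread, so the raised bulk of the metastatic arrays lowers it where that shift is not removed evenly.

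Over the 76 named differences that passed, none reversed under any setting tried: 1363 results kept their side of the threshold and 612 lost it, while 160 results of named differences that had not passed gained it. CENPB and RNA polymerase for metastatic minus control and for both patient groups, TRPT1 for metastatic minus control and CENPB for nonmetastatic minus control passed under every setting run. The other called differences lost the threshold under at least 1 setting, except BC046151.1 for metastatic minus control and both patient groups. The replicate block ended no call. Low signal limits STK17A, DYRK3, TTK, COPZ1, LARP6, SMAD3, PRKD2, BC014975.1 and BC033035.1, which were not above background on every array.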

Other observations

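The tests of other splits were set before their results were seen, and the families and preparations described here were chosen after the values were seen.

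Of the receptor-regulated SMAD proteins, which share homologous domains, SMAD3 and SMAD2 passed between the patient groups and SMAD1 did not; the family was not tested as a list. SMAD3 stood at 11.13 ± 0.03 in the nonmetastatic group, 9.53 ± 0.04 in the metastatic and 9.77 ± 0.08 in the control group (log2, SD, n = 3), and SMAD2 at 11.92 ± 0.40, 10.57 ± 0.14 and 10.63 ± 0.17. SMAD1 stood at 10.95 ± 0.17, 10.28 ± 0.28 and 10.32 ± 0.06, with a metastatic minus nonmetastatic difference of -0.67 that did not pass in limma (adjusted p = 0.489, or 0.317 with the block). The metastatic minus nonmetastatic difference kept its sign under every scaling tried, but shrank with no scaling, to -1.15 for SMAD3, -0.73 for SMAD2 and -0.16 for SMAD1, in the value table, to -1.22, -0.61 and -0.21, and with a robust linear model on control spots, to -1.26, -0.75 and -0.33. The myosin light chain kinases MYLK2 and MYLK3, both printed under catalogue numbers, differed by -2.17 and -1.59 between the patient groups, by -1.90 and -1.28 with the control-spot model, -1.58 and -1.01 with no scaling and -1.40 and -0.89 in the value table, and MYLK3 passed only with the block (adjusted p = 0.229 without and 0.00941 with it).

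Among the 26 purified antigens, a list chosen after the data were seen, those that passed were few. Adjusted over the list alone, RNA polymerase was brighter and CENPB was dimmer for metastatic minus control, and RNA polymerase and the influenza A preparation were brighter and CENPB was dimmer for nonmetastatic minus control (adjusted p = 0.00692, 0.0357 and 3.42e-07). Among purified antigens that did not pass, Jo-1 measured 8.85 ± 0.46 in the control and 8.80 ± 0.39 in the metastatic group, and La 9.12 ± 0.58 and 8.89 ± 0.41. The citrullinated preparation named CCP_1BSA differed by -1.09 for both patient groups minus control, and passed only with the block (adjusted p = 0.0219), as it did for the metastatic and the nonmetastatic group alone (0.0462 and 0.0475).

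Catalogue features were over-represented by Fisher's exact test among the calls against the control group. They made 4 of 241 against 21 of the other 7976 features for metastatic minus control (adjusted p = 0.0112), 3 against 13 for nonmetastatic minus control (0.0168) and 4 against 15 for both patient groups (0.00737). For metastatic minus nonmetastatic, 2 against 14 did not pass (0.0785). Purified antigens made 2 of 26 against 23 of the other 8191 features for metastatic minus control, and 2 against 17 for both patient groups (Fisher's exact test, adjusted p = 0.00737 for each). For nonmetastatic minus control and for metastatic minus nonmetastatic, 1 against 15 did not pass (0.0566 for each). The calls against the control group share CDK1, STK17A, DYRK3 and CENPB and the same control arrays, so they are not separate findings. Features of a slide are not independent replicates.

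Before scaling, the metastatic minus control difference differed with the control signal, from a median of 0.24 (log2) in the dimmest of 10 groups of features to 0.77 in the ninth and 0.72 in the brightest, while the nonmetastatic minus control difference ran between 0.05 and 0.14. The 30 features reactive on at least 2 control arrays had a median metastatic minus control difference of -0.12. The 33 features reactive on at least 2 nonmetastatic arrays had a median metastatic minus control difference of -0.01.

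Other splits of the arrays were run for each count. For each pair of groups the 6 arrays make 10 splits, too few for a share under 0.05. For metastatic minus control, 2 of the 10 splits gave at least the 25 features of the real split, the highest other giving 30. That split kept 2 scan-day pairs together and put both lot 2 arrays on the same side. For nonmetastatic minus control 1 of 10 did so (16 against 7 in the highest other), and for metastatic minus nonmetastatic 1 of 10 (16 against 0). Of the splits that part all 3 day pairs, as the real split does, there are 4 per comparison, and the others gave 0 without and 0 with the replicate block, against 49, 44 and 32 with it. For both patient groups minus control, 5 of 100 drawn regroupings gave at least 19 features, so chance is not excluded there. The highest, 875 features, set the 3 arrays of lot 2, which are those of scan day 3, against the rest as the control. In all 4 of the other regroupings that reached 19, with 373 to 875 features, the 3 lot 2 arrays formed a group of their own, as the control or as a patient group. Of the 96 drawn regroupings that spread the lot 2 arrays over at least 2 groups, the real grouping alone reached 19, and the next gave 13. Such counts point to a structure of the arrays by lot or scan day, which these splits do not tell apart. The 11 drawn regroupings that part all day pairs, the real one included, gave at most 0 in the others. With the scan day as a block and the 6 patient arrays as a single group, all 27 ways to pick an array of each day as the control were run. Only 1 of the 27, the real pick, gave as many features as the real 24, which is the smallest share possible. The highest other gave 21, with the nonmetastatic arrays as the control. A chance pick of arrays is thus argued against for that fit at a share under 0.05. The test asks only whether arrays of a group resemble each other. A chance difference between pools or donors is not excluded by it.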
